A study of Arabidopsis thaliana with 8 samples.

How the data were processed

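Total RNA was taken from the aerial parts of WT and yda-2 rosettes grown in soil under constant light at 22 °C, per the labels, with 4 biological replicates per genotype that were grown and harvested at different times. Per the labels, the RNA was labelled and hybridized to Affymetrix AtGenome1 arrays and the average signal of all 8 arrays was scaled by the authors to a target of 500. The deposited values are signal intensity on a linear scale, 1 value per probe set and array, with no detection calls. The summary algorithm and software are not given in the sources used here. The mean of each array after leaving out 2% of the values at each end lay between 500.4 and 500.9, so the scaling is visible in the values. The scaling equalizes the mean and not the shape of the distribution, so bright probe sets on arrays with a compressed range can differ between arrays with no change in the RNA. Column names matched the samples, and groups and replicate numbers were taken from the titles.

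Signals were used as log2(signal + 16), and fold changes are on that scale, which understates changes of dim probe sets. The 50 control probe sets were left out of the tests. Probe sets with a mean signal of at least 100 over all 8 arrays were kept, 4788 in number or 58.1% of the probe sets without controls. No further normalization was done. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with the intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, with 1 probe set per gene, the brightest, and with the correlation estimated from the residuals beside it. Lists with fewer than 5 measured genes were given no set test, and adjustment was over the lists of each kind. The robust setting has no counterpart in camera and was not run for lists. Array controls were compared by an exact permutation test over 70 assignments and by an exact paired test over 16 sign changes. Figures were drawn with matplotlib 3.10.9.

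The pairing was checked on the values. The deviations of same-numbered WT and yda-2 arrays from their group means correlated, across probe sets, at 0.596, 0.296, 0.324 and 0.577 for replicates 1 to 4, and 7 of the 8 arrays correlated best with the array of the same number. The labels give replicates as tissue grown and harvested at different times, and the numbers were therefore taken to pair the arrays. The fit without the block was chosen as the main one before the data were examined, and blocked values are given beside it where they change a call or move a count.

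Names come from the platform's gene annotation, updated through gene identifiers to the symbols of assembly TAIR10.1. Of the probe sets without controls, 3794 have 1 gene, 70 have several and 4383 have none in that table. Of the 1-gene probe sets, 3784 matched the updated gene table. Among tested probe sets, 2035 have 1 gene, for 1923 genes, and no name was taken from a probe set with several. A single name in the annotation does not exclude that probes also bind transcripts of similar genes, which was not tested. An unnamed probe set is given by its identifier. The annotation's names mean that 32 of 592 genes on the 23 lists fixed before the data were examined were tested, and 227 of 229 genes on the 18 added lists. A planned list of cytosolic ribosomal proteins needed gene descriptions and was not used here. YDA, also planned, was not analysed here. Coordinates are not given.

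The text names, by a rule written before the data were examined, every measured stomatal lineage gene and up to 12 genes with the largest rise and 12 with the largest fall past the threshold. Where fewer passed, it names those with the smallest unadjusted p up to 6 in that direction. It also names up to 4 genes with the smallest p of each list that passed or had a called gene. The unnamed probe sets are named because they are the called ones. Genes of lists with few members, and the genes in the closing part, were chosen after their values were seen.

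On data simulated from the 4788 probe sets, with 200 changed probe sets in each of 10 simulations, the fit without the block recovered 3.4% of 2-fold and 65.7% of 4-fold changes, and 0.576% of its calls were false. The fit with the block recovered 33.6% and 80.8%, and 3.05% of its calls were false. On simulated lists of 16 genes, the blocked set test found 100% of lists shifted 2-fold and 4% of unshifted lists. Noise was drawn independently for each probe set, so the 4% does not cover lists whose genes vary together. The chloroplast photosynthesis list below is such a list, with an estimated correlation of 0.25 with the block. Alternatives covered pseudocounts of 1 and 64, no filter and a filter of 200, quantile normalization, median centring, no trend, robust eBayes, array weights, the replicate block, a 2-fold minimum, exact permutation per probe set and leaving out each array. Added after the data were seen were a block for the array set, each array set alone, the alternatives together with the block, and leaving out each pair.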

Results

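RNA from the aerial parts of Arabidopsis thaliana rosettes was compared between wild type (WT) and yda-2, a mutant allele of YODA (YDA). YDA encodes a mitogen-activated protein kinase kinase kinase that restrains the formation of stomata in the leaf epidermis. The comparison asks which transcripts differ in abundance between the mutant and wild type in whole rosettes before bolting. Each genotype was measured on 4 Affymetrix AtGenome1 arrays, each array carrying an independent biological replicate, and same-numbered replicates of the genotypes are called a pair here. The table held 8297 probe sets on 8 arrays, of which 50 were array controls. A total of 4788 probe sets had a mean signal of at least 100 and were tested. The median signal per array lay between 125.7 and 190.3, the highest in WT replicate 2. The number of arrays limits the precision of every value below.

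The arrays differed more by replicate than by genotype. The first principal component of the log2 signals held 44.2% of the variance and parted the arrays of replicates 1 and 2 from those of replicates 3 and 4. The maximum signal lay between 22519 and 33920 in the former and between 6226 and 10422 in the latter. Both array sets held both genotypes equally. The second component, with 20.5% of the variance, parted WT replicate 2 from the other arrays. That array had a mean correlation of 0.819 with the others across probe sets, which are not independent, against 0.873 to 0.903 for the remaining 7.

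**Figure D1:**
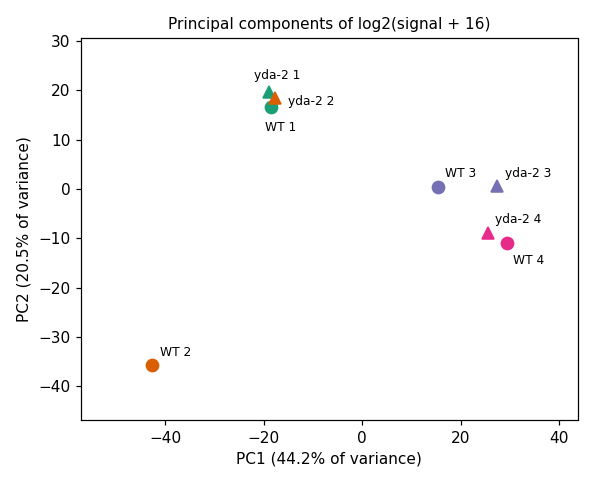
Scores of the 8 arrays on the first principal component (x axis, 44.2% of variance) and the second (y axis, 20.5% of variance) of log2(signal + 16) over 4788 probe sets. Circles are WT, triangles are yda-2 and each colour is a replicate number. Replicates 1 and 2 lie left of 0 and replicates 3 and 4 right of 0, with WT 2 at the lower left.

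The transcripts that differed most were more abundant in yda-2. Probe set 16614_s_at rose from a signal of 14.3 ± 10.8 in WT to 296.3 ± 100.2 in yda-2 (SD, n = 4 each), and probe set 16888_at from 90.0 ± 30.5 to 408.1 ± 19.8. Their log2 fold changes were 3.38 (SE 0.43, adjusted p = 0.0286) and 2.04 (SE 0.28, adjusted p = 0.0340), and both were higher in yda-2 in 4 of 4 pairs. The WT signals of 16614_s_at, 3.4 to 25.7, lay near the pseudocount of 16 and have no detection calls, so the size of its fold change is not fixed by the data: it was 4.57 with a pseudocount of 1 (adjusted p = 0.112) and 2.17 with 64 (adjusted p = 0.0178). Neither probe set has a gene in the table of names used here. These 2 probe sets, 2 higher and 0 lower, were all that passed an adjusted p of 0.05 in limma without the pairing. At an unadjusted p under 0.05 there were 118 higher and 36 lower probe sets, together 3.22% of those tested. That is below the share of 0.05 expected on average with no difference, a value that takes no account of the pairing. In the other groupings of the arrays that part all 4 pairs, 28 to 103 probe sets were at that p, against 154 in the real one. Such groupings are too few to exclude chance. With the pairing in the fit, 7.10% of the tested probe sets were at an unadjusted p under 0.05. After median centring of the arrays, without the pairing, there were 100 higher and 74 lower. With the pairing there were 216 higher and 124 lower before centring, 165 and 176 after it, and 188 and 172 after quantile normalization. An excess of higher probe sets with the pairing thus did not outlast median centring. The 2 calls made without the pairing ended after median centring, with adjusted p = 0.0644 and 0.0910. After quantile normalization the adjusted p was 0.0677 for both. The fold changes stayed at 3.33 and 2.00 after median centring. The count fell to 0 without any 1 of WT replicates 3 and 4 and yda-2 replicates 1 to 4, and to 1 without WT replicate 2.

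With the replicate pairs as a block, 9 probe sets were higher in yda-2 and 0 were lower, and 3 of the 9 have a single named gene. CHI (AT2G43570), which encodes a putative chitinase, rose from 386.0 ± 107.7 to 1064 ± 231 (SD, n = 4), a log2 fold change of 1.44 (blocked adjusted p = 0.0333). AT1G09500, which encodes a reductase of the cinnamyl alcohol dehydrogenase-like family, rose from 134.8 ± 62.7 to 595.7 ± 323.0, a log2 fold change of 2.00 (blocked adjusted p = 0.0333). AT2G05540, which encodes a glycine-rich protein, rose from 428.5 ± 66.6 to 1375 ± 519, a log2 fold change of 1.59 (blocked adjusted p = 0.0436). Without the block their adjusted p-values were 0.145, 0.375 and 0.145. Probe sets 19171_at, 14978_at, 16053_i_at and 16150_at, which have no gene in the table of names, made up the rest of the 9 with 16614_s_at and 16888_at. Their log2 fold changes were 1.74, 1.53, 1.28 and 1.39. The signal of the bacterial and phage control transcripts was lower in yda-2 in the same 4 of 4 pairs. The blocked count was 0 without pair 1, without pair 3 and without pair 4, and 28 without pair 2, which holds the WT replicate 2 array. It was 0 after median centring or quantile normalization, where the smallest adjusted p was 0.0543 and 0.0565. All 9 stayed above 0 after both, and the blocked log2 fold changes of 16614_s_at and 16888_at, 3.38 (SE 0.43) and 2.04 (SE 0.26) before, were 3.33 (SE 0.41) and 2.00 (SE 0.26) after median centring and 3.05 (SE 0.40) and 1.93 (SE 0.25) after quantile normalization.

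**Figure D2:**
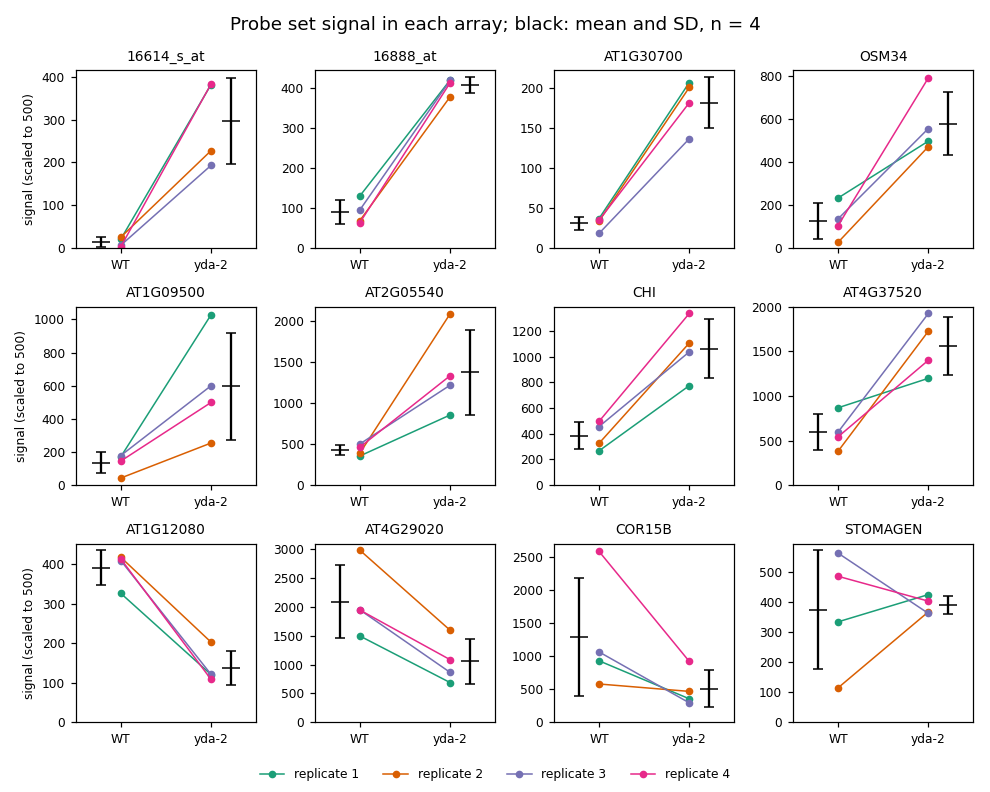
Signal of 12 probe sets (y axes, arbitrary units scaled to 500, each from 0) in WT and yda-2. Coloured points are arrays, lines join same-numbered replicates, and black bars are the mean ± SD (n = 4). The yda-2 arrays of CHI lie between 774.5 and 1336 and its WT arrays between 267.0 and 496.0, while those of STOMAGEN overlap.

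Among named genes that did not pass without the block, the smallest unadjusted p-values on the rising side also belonged to AT1G30700, OSM34 and AT4G37520. AT1G30700, a berberine bridge enzyme-like gene, had a signal of 31.0 ± 8.5 in WT and 181.1 ± 31.7 in yda-2 (SD, n = 4), a log2 fold change of 2.07 with adjusted p = 0.145. Its WT signals, 18.4 to 36.9, lay near the pseudocount, and the fold change was 2.54 with a pseudocount of 1 and 1.36 with 64. OSM34, an osmotin of the thaumatin-like family, had 125.8 ± 85.1 and 579.1 ± 145.6, a log2 fold change of 2.29 with adjusted p = 0.168. AT4G37520, a class III peroxidase, had 597.2 ± 202.6 and 1563 ± 325, a log2 fold change of 1.40 with adjusted p = 0.168. With the block their adjusted p-values were 0.0848, 0.0641 and 0.109, and the first 2 passed in the blocked fit without pair 2 (adjusted p = 0.0146 and 0.0231). With array weights all 3 passed without the block (adjusted p = 0.0174, 0.0213 and 0.0366) and with it (adjusted p = 0.00772, 0.00839 and 0.0379). Over all alternatives with the block their adjusted p reached 0.568, 0.374 and 0.611. AT1G30700 also passed without the intensity trend (adjusted p = 0.0163). The groups did not overlap for any of these 3 genes, nor for CHI, AT1G09500 and AT2G05540. Over all tested probe sets, 83 had all yda-2 values above all WT values and 31 had all below. Random grouping of unpaired arrays gives 2.86% of probe sets, or 136.8, a value that takes no account of the pairing. The real split had 114 in all, and the other splits that part all 4 pairs had 29 to 73.

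No named gene fell past the threshold with or without the block over all 8 arrays at equal weight. The smallest unadjusted p-values on the falling side belonged to AT1G12080, AT4G29020, AT2G34060, MSRB6, COR15B and CYP71B29. AT1G12080, which encodes a protein related to vacuolar calcium-binding proteins, had a signal of 391.2 ± 43.7 in WT and 137.8 ± 43.4 in yda-2 (SD, n = 4). Its log2 fold change was -1.44 (SE 0.27, adjusted p = 0.145, and 0.0726 with the block). AT4G29020, which encodes a glycine-rich protein, had 2095 ± 631 and 1057 ± 394, and a log2 fold change of -0.9998 (blocked adjusted p = 0.0726). COR15B, a cold-regulated chloroplast protein gene, had 1286 ± 886 and 506.2 ± 283.1, and a log2 fold change of -1.24 (blocked adjusted p = 0.146). AT2G34060, a class III peroxidase gene, MSRB6, a methionine sulfoxide reductase gene, and CYP71B29, a cytochrome P450 gene, had log2 fold changes of -0.84, -0.90 and -0.80, with blocked adjusted p-values between 0.471 and 0.547. In the blocked fit without pair 2, which holds the WT replicate 2 array, AT1G12080, AT4G29020 and COR15B passed (adjusted p = 0.0146, 0.0422 and 0.0102). Without the block AT1G12080 passed with array weights (adjusted p = 0.0174), the 1 lower probe set among 11 called there. In the blocked fit with array weights MSRB6 passed with AT1G12080, AT4G29020 and COR15B (adjusted p = 0.0471). Without pair 3 the adjusted p of all 4 was 0.473 or higher.

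Few genes of the stomatal pathway could be followed. YDA's own transcript was not analysed here, so the genotype labels have no check from the targeted gene, and a mutant allele need not change its transcript. Of the 21 stomatal lineage genes, 1 was measured, that is, had a tested probe set with its name. Measured is used in this sense for all lists. As 2713 tested probe sets have no gene in the table of names, other members may be on the array without a name. STOMAGEN, a mesophyll-derived peptide that promotes stomatal formation, had a signal of 374.4 ± 197.8 in WT and 389.4 ± 29.9 in yda-2 (SD, n = 4). Its log2 fold change was 0.25 (SE 0.41, adjusted p = 1.00), and it turned to -0.21 without WT replicate 2, where STOMAGEN was at 114.3. The lists of guard cell genes, mitogen-activated protein kinase genes, epidermis and cuticle genes, flowering genes, vascular genes, flavonoid genes, gibberellin and brassinosteroid genes, oxidative stress genes and root genes had 0 measured members each.

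Of the 23 gene lists fixed before the data were examined, photosynthesis alone had the 5 measured genes needed for a set test. Its 6 measured genes had a mean log2 fold change of -0.30, 5 below 0 and 1 above, and 0 passed, over all probe sets or adjusted over the list alone. The list did not pass (limma camera, adjusted p = 0.315, and adjusted p = 0.0554 with the block). It was the only list of its kind tested, so every adjusted p given for it equals the unadjusted p. With an estimated correlation, 0.47 and with the block 0.39, the values were adjusted p = 0.593 and, with the block, adjusted p = 0.335. The values below on leaving out arrays or pairs used the preset correlation of 0.01. Without 1 array the mean turned to 0.12 (WT replicate 1), 0.05 (WT replicate 2), 0.13 (yda-2 replicate 3) and 0.20 (yda-2 replicate 4), while the list passed at -0.85 without yda-2 replicate 1 (adjusted p = 0.0187) and at -0.9985 without WT replicate 4 (adjusted p = 0.00972). Leaving out 1 array left the genotypes unequal between the array sets, so these values do not separate genotype from array set. With the block the list passed without pair 1, 2 or 4, and its mean was 0.06 without pair 3. The other lists with any measured gene had 1 to 4. The 4 cold and drought genes had a mean log2 fold change of -0.60, with 0 past the threshold adjusted over the list alone and 2 with the block, COR15B and KIN2. KIN2, a cold-induced gene, had a log2 fold change of -0.47 (blocked adjusted p over all probe sets = 0.531). A larger added list, 16 genes of cold and drought response, had a mean of 0.13, with 10 above 0 and 6 below. The 2 cell division genes had a mean of -0.41, with 1 past the threshold adjusted over the list alone with the block. That gene was PRL, the MCM7 subunit of the replicative helicase, at 1053 ± 141 in WT and 693.2 ± 190.3 in yda-2 (SD, n = 4), a log2 fold change of -0.62. The 3 auxin genes had a mean of 0.55, with 0 past adjusted over the list alone and 1 with the block, WES1, an auxin-conjugating GH3 enzyme gene, at 0.89. With the block, adjusted over the list alone, 1 gene each of the cell expansion, senescence and glucosinolate lists also passed, with 4, 2 and 3 measured genes. These were EXPA8, an expansin gene, at -0.79, WRKY6, a transcription factor gene, at 0.71 and AOP3, a glucosinolate side-chain gene, at -0.59. Over all probe sets 0 genes of these lists passed. The 2 meristem genes averaged -0.07, and WRKY53, THI2.1, Hsp70-2, STZ and GI, the single members of the pathogen, jasmonate, heat shock, touch and circadian lists, had log2 fold changes of 0.05, 0.03, 0.57, 0.13 and 0.26.

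A further 18 lists were drawn from the names in the gene table after it was seen and before any difference between the genotypes was computed. None of the 18 passed without the block. With the block, the 16 genes of chloroplast photosynthesis were lower in yda-2 as a list, with a mean log2 fold change of -0.26, 12 genes below 0 and 4 above (camera, adjusted p = 0.0292, and adjusted p = 0.682 with an estimated correlation). With the block the list did not pass after quantile normalization (mean -0.21, adjusted p = 0.297), without a filter (adjusted p = 0.0585) or without the intensity trend (adjusted p = 0.0822). In the same pairs the ubiquitin 3' over 5' ratio was higher in yda-2 in 4 of 4, by 0.34 on the log2 scale, and the control transcripts were lower in 4 of 4, at -0.40. Of the 16 genes, 0 passed over all probe sets and 1 passed adjusted over the list alone. That gene was LHCB4.3, a light-harvesting antenna protein gene, at 1616 ± 825 in WT and 729.2 ± 334.9 in yda-2 (SD, n = 4), a log2 fold change of -1.08 (blocked adjusted p = 0.119). PSBW and HPR, genes of a photosystem II subunit and a photorespiratory reductase, were at -0.34 and -0.34, and PSAE-1, of a photosystem I subunit, was at 0.20. None of these 3 passed in any fit, and on leaving out 1 array PSBW lay between -0.62 (WT replicate 4) and -0.13 (WT replicate 2), HPR between -0.60 (WT replicate 4) and -0.11 (WT replicate 1) and PSAE-1 between -0.11 and 0.35. The mean of the list was -0.04 within the arrays of replicates 1 and 2 and -0.48 within those of replicates 3 and 4. In the latter pairs the maximum signal of the array was lower in yda-2 (6969 against 10422, and 6226 against 7857), and more probe sets lay above the midpoint of the maximum (354 against 217, and 384 against 289). The list did not pass without pair 3, and its mean turned to 0.003, 0.007 and 0.07 without WT replicate 1, yda-2 replicate 3 and yda-2 replicate 4. Without the block it passed at -0.59 without yda-2 replicate 1 (adjusted p = 0.0128). It also passed at -0.53 without yda-2 replicate 2 (adjusted p = 0.0111) and at -0.67 without WT replicate 4 (adjusted p = 0.00687). Values with 1 array left out have the genotypes unequal between the array sets and do not separate genotype from array set.

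The 8 genes of division and chromatin had a mean log2 fold change of -0.24, 7 below 0 and 1 above, and did not pass (camera, adjusted p = 0.0971, and 0.0643 with the block). In fits without the block, the list passed without WT replicate 4 (adjusted p = 0.0378) and without yda-2 replicate 3 (adjusted p = 0.0422). In each of these the list was tested with the genotypes unequal between the array sets. With an estimated correlation over all 8 arrays, camera gave it an adjusted p = 0.789, and 0.682 with the block. PRL and the histone H3 gene AT5G65360, at -0.42, were the lowest. The 19 defence genes had a mean of 0.22 and a median of 0.03, and did not pass (adjusted p = 0.419, and 0.338 with the block). Their mean was 0.07 without WT replicate 4, 0.12 without yda-2 replicate 1 and 0.36 without WT replicate 1. CHI passed over all probe sets with the block, and adjusted over the list alone 2 passed with it and 1 without. AT5G64120, a class III peroxidase gene, had a log2 fold change of 1.62 with a signal of 158.7 ± 124.6 in WT and 417.4 ± 277.5 in yda-2 (SD, n = 4), and did not pass over all probe sets (blocked adjusted p = 0.337). Its log2 fold change was 0.88 without WT replicate 2, where its signal of 10.3 lay under the pseudocount, and 2.03 without WT replicate 1. CML41, a calmodulin-like gene, was at 0.81. The other added lists did not pass in either fit. Their mean log2 fold changes were -0.19 for chlorophyll synthesis, 0.02 for cell wall, 0.06 for cytoskeleton, 0.13 for cold and drought response, -0.05 for redox, 0.14 for UDP-glycosyltransferases and 0.04 for the vacuolar proton ATPase. They were 0.20 for ATG8 autophagy genes, 0.10 for the secretory pathway, 0.14 for the ubiquitin pathway, 0.08 for hormone response, -0.03 for leaf patterning, 0.03 for sugar and starch, 0.30 for mitochondrial metabolism and 0.07 for RNA synthesis and processing. Adjusted over the list alone, 1 gene of cold and drought response passed without the block and 3 with it. Of the redox genes, 0 passed that way without the block and 1 with it.

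The array controls passed no exact test between the genotypes. The median log2 signal of an array was 8.69 ± 0.14 in WT and 8.74 ± 0.16 in yda-2 (SD, n = 4, exact permutation test, two-sided p = 0.714). The log2 ratio of the 3' over the 5' probe set of GAPDH was 0.24 ± 0.50 and 0.28 ± 0.50 (n = 4, exact permutation p = 1.00). That of ubiquitin was -0.45 ± 0.41 and -0.11 ± 0.52 (n = 4, exact permutation p = 0.343), and it was higher in yda-2 in 4 of 4 pairs. The log2 signal of the bacterial and phage control transcripts was 10.35 ± 0.97 and 9.95 ± 0.92 (n = 4, exact permutation p = 0.514), and it was lower in yda-2 in 4 of 4 pairs. The smallest p this design allows is 0.0286. In an exact paired test over the 16 sign changes of the pair differences both of these controls had p = 0.125, the smallest that 4 pairs allow.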

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

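All tests of explanations in this part were chosen after the results were seen. Among 84 groups of 4 arrays tested for an outlying array (named probe sets and array measures), 9 had an array farther from the rest than Dixon's 95% critical value, where chance gives about 1 in 20, or 4.2. The median signal of WT replicate 2 was 190.3 against 125.7 to 131.9 in the other WT arrays. AT2G20870 was at 1531 in WT replicate 2 and at 66.3 to 151.3 in the other WT arrays. AT1G12080 was at 325.9 in WT replicate 1 against 408.8 to 417.1, and at 202.3 in yda-2 replicate 2 against 108.0 to 120.7. Probe set 16888_at was at 378.7 in yda-2 replicate 2 against 413.7 to 420.5, and PSAE-1 at 12596 there against 4838 to 6090. AT5G64120 was at 830.4 in yda-2 replicate 3 against 241.3 to 324.2. In WT replicate 1, CML41 was at 1157 against 631.0 to 671.3 and WRKY6 at 515.6 against 218.8 to 256.8.

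The 9 probe sets higher in yda-2 with the block were weighed against a single outlying array, WT replicate 2. The blocked fit over all probe sets without pair 2, which never uses that array, called 28 probe sets, and 9 of the 9 were among them, which argues against that array as the sole cause. In these arrays the 9 were higher in both array sets, with 36 of 36 pair differences above 0, from 0.97 to 4.36 on the log2 scale. Picking them over all 4 pairs favours such values, so they are no separate test. The control transcripts were lower in yda-2 in 4 of 4 pairs, so a difference in labelling or hybridization between the genotypes stays open and was not tested. Chance stays open too: the 8 splits that part all 4 pairs are too few for a share under 0.05, and 1 of them, the real one, gave 9 calls while the highest other gave 0.

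The arrays of replicates 1 and 2 stood apart from those of replicates 3 and 4. Bacterial and phage control transcripts, which are not made by the plants, were higher in the former by 1.62 on the log2 scale (10.96 ± 0.28 against 9.34 ± 0.26, SD, n = 4, exact permutation p = 0.0286, the smallest possible). The nearest arrays of the sets were 1.06 apart, and differing labelling, hybridization or scanning is a candidate explanation. The controls were read after each array was scaled to its mean signal. They therefore cannot show how much of the difference in plant transcripts came from growth and harvest time. Probe sets above the midpoint of an array's maximum numbered 51 to 91 per array in replicates 1 and 2 and 217 to 384 in replicates 3 and 4. A share of the difference from the plants' growth times stays open and was not tested.

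Other splits of the 8 arrays put the counts in scale. Without the block, 2 of the 35 splits gave at least 2 called probe sets, so chance is not excluded. The other one follows the array sets and called 735 probe sets, 15.4% of those tested, which points to a structure of the samples. With the array set as a block, 4 probe sets were called. For the 154 probe sets at an unadjusted p under 0.05, 20 of 35 splits gave as many, with 1553 in the highest other. For the 76.6% of these that were higher, 8 of 35 splits gave as one-sided a share, with 79.7% in the highest other, so chance is not excluded for either. Of lists past the threshold the real split had 0, so all 35 of 35 splits have as many by construction and nothing follows for chance. The highest other split gave 1 of the lists fixed first and 2 of the added lists. The numbers were taken to pair the arrays, and many of the 35 splits keep pairs together. Among the 8 splits that part all pairs, without the block 1, the real one, gave as many as the 2 called probe sets, with 0 in the highest other, 1 gave as many as the 154, with 103 in the highest other, and 4 gave as one-sided a share. With the block, 1 gave as many as the 340 probe sets at an unadjusted p under 0.05, with 223 in the highest other, and 3 gave as many as the 1 added list, with 2 in the highest other. Those 8 splits are too few for a share under 0.05.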

How the results depend on the processing

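Alternatives that pair the block with another choice, the array-set alternatives and the alternatives run on added lists were chosen after seeing the data. The count of 2 called probe sets was 0 with a pseudocount of 1, with a filter at 200, with quantile normalization, with median centring and by exact permutation per probe set, whose smallest p of 0.0286 cannot pass the adjustment. It was 1 with no filter and 11 with array weights, 10 higher and 1 lower. It was 9 with the replicate block, 4 with an array-set block and 0 in the arrays of replicates 1 and 2 only. Leaving out 1 array gave 0 to 2. With the other alternatives the count was 2 or 3, not always of the same probe sets: in the arrays of replicates 3 and 4 only, 16888_at was not called and AT2G20870 was. The blocked count of 9 was 0 with a pseudocount of 1, with no filter, with quantile normalization and with median centring, 4 without the intensity trend and 41 with array weights, 32 higher and 9 lower. Leaving out 1 pair gave 0 to 28. All 9 were among the 12 called with a pseudocount of 64, the 9 with robust eBayes and the 41 with array weights, 8 among those with the filter at 200 and 3 among those without the trend. The cause was not tested, except that leaving out arrays leaves fewer samples and that a filter at 200 drops dim probe sets.

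Of the lists fixed first, 0 passed. Photosynthesis passed, making 1, in the arrays of replicates 3 and 4 only, and 1 passed with the block together with all probe sets per gene or a pseudocount of 64. Leaving out 1 array or 1 pair gave 0 to 1, and the mean of photosynthesis then ranged from -0.9985 to 0.20, and from -0.50 to 0.0615 on leaving out 1 pair with the block. Of the added lists, 0 passed without the block, 1 with the replicate block and 1 in the arrays of replicates 3 and 4 only, and leaving out 1 array gave 0 to 2. The blocked count of 1 was 0 with the estimated correlation, with no filter, with quantile normalization and without the trend, 2 with array weights, and 0 to 2 on leaving out 1 pair. The mean of chloroplast photosynthesis ranged from -0.67 to 0.0652 on leaving out 1 array. Without the block, leaving out 1 array left the genotypes unequal between the array sets, so those ranges do not separate genotype from array set. Of gene and list calls over all probe sets or lists, the block changed no other, and calls adjusted over a list alone are given with the lists. The cause was not tested.

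Of 749 values of 36 named probe sets under the alternatives, 5 turned sign, in STOMAGEN and PSAE-1. STOMAGEN was at -0.21 with array weights and -0.44 in the arrays of replicates 3 and 4 only, and between -0.21 and 0.51 on leaving out 1 array, and PSAE-1 between -0.11 and 0.35. A further 18 values passed the threshold and 24 lost it, and 702 kept direction and side. Of 461 values with the block and another choice or without 1 pair, 24 passed, 20 of them with array weights or without pair 2, 69 lost it and 2 turned sign. These were PSAE-1 at -0.00568 with array weights and STOMAGEN, between -0.18 and 0.54 on leaving out 1 pair. The log2 fold change of 16614_s_at lay between 2.17 and 4.57 and that of 16888_at between 1.64 and 2.22 under all alternatives that gave a value. On leaving out 1 array, the difference in array median was between -0.0208 and 0.0890, that in the GAPDH ratio between -0.11 and 0.27, that in the ubiquitin ratio between 0.08 and 0.51 and that in the control transcripts between -0.70 and -0.0717. The alternatives planned for YDA gave no value. Dim probe sets limit the precision: between 10.7% and 20.9% of probe sets per array lay under a signal of 16, and there are no detection calls.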

Other observations

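All genes and tests in this part were chosen after the values were seen. AT1G22690, a gene of the GASA family whose promoter is active in guard cells, had a signal of 720.1 ± 196.1 in WT and 1596 ± 470 in yda-2 (SD, n = 4), a log2 fold change of 1.13 (SE 0.29, limma adjusted p = 0.473, and 0.0584 with the block). It was higher in yda-2 in 4 of 4 pairs and the groups did not overlap, but it did not pass in either fit. With the block its adjusted p lay between 0.00499 with array weights and 0.407 over the alternatives, and it passed without pair 2 (adjusted p = 0.0376). The list of guard cell genes had 0 members with a named and tested probe set, so AT1G22690 could not be set beside others of its kind. CCS, the copper chaperone of superoxide dismutase, was at 958.1 ± 223.5 and 1880 ± 399 (log2 fold change 0.96, blocked adjusted p = 0.155, and between 0.0471 with array weights and 0.731 over the blocked alternatives). AT2G38870, a serine protease inhibitor gene, was at 818.5 ± 121.7 and 1586 ± 340 (log2 fold change 0.93, blocked adjusted p = 0.125, and between 0.0291 with array weights and 0.495 over the blocked alternatives). TBL37, a trichome birefringence-like gene, and UGT87A2, a glycosyltransferase gene, had log2 fold changes of 0.74 and 0.83, and the groups did not overlap for these 4 genes.

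Genes with large mean differences and a wide spread were not called with or without the block over all 8 arrays at equal weight. AT4G33150, of the lysine catabolic enzyme LKR/SDH, had a signal of 82.4 ± 66.2 in WT and 271.4 ± 121.8 in yda-2 (SD, n = 4), a log2 fold change of 1.72. SAG29, a senescence-associated sugar transporter gene, was at 96.5 ± 62.7 and 296.1 ± 178.0, a log2 fold change of 1.48. AT4G38540 was at 95.2 ± 68.6 and 302.9 ± 127.6, a log2 fold change of 1.68 (blocked adjusted p = 0.125, and between 0.0268 with array weights and 0.623 over the blocked alternatives). AT2G20870 had the widest spread of these, 472.6 ± 706.8 and 2122 ± 1490, a log2 fold change of 2.78 (blocked adjusted p = 0.264). Its log2 fold change was 0.90 within the arrays of replicates 1 and 2 and 4.66 within those of replicates 3 and 4, where it passed (adjusted p = 0.0329). It also passed with array weights (adjusted p = 0.0366) and in the blocked fit without pair 2 (adjusted p = 0.0146), and blocked adjusted p-values ranged up to 0.848. In yda-2 it was at 437.3 in replicate 1 and at 4067 in replicate 4.

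Class III peroxidases, enzymes of the cell wall and apoplast, drew attention because AT4G37520, AT2G34060 and AT5G64120 were among the genes named above. Of 73 loci written down from general knowledge after the differences were seen, 17 were tested. At an unadjusted p under 0.05, 4 were higher in yda-2 and 1 was lower, 29.4% of the family against 2.79% of 1903 other named genes. AT2G37130 was at 697.4 in WT and 1280 in yda-2 (log2 fold change 0.91), and AT4G33420 at 110.5 and 211.4 (0.85). A hypothesis is that peroxidase genes may change more often than others in yda-2. The 3 genes that drew attention cannot test it. Without them 2 of 14 were at that p, and Fisher's exact test over genes, which are not independent, gave p = 0.0590, and 0.00723 with the block. In 4 of the 35 splits of the arrays, the real one included, the ratio of these shares without the 3 genes was as high, at 5.13 against 12.4 in the highest other, so chance is not excluded and the hypothesis stays open. Among the 8 splits that part all pairs, the highest other ratio was 5.23, above the real one. Splits were not run for the blocked value. A shift of the family in 1 direction was not found: 11 of the 17 were above 0 and 6 below, with a mean log2 fold change of 0.23. Camera on this list alone gave an unadjusted p = 0.0999, and unadjusted p = 0.177 with the block. With an estimated correlation camera gave an unadjusted p = 0.127, and unadjusted p = 0.340 with the block.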
